A study of Homo sapiens with 15 samples.

How the data were processed

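Total RNA of IMR90 cells, an established line of human fetal lung fibroblasts, was extracted with a column kit and DNase, made into libraries with the KAPA RNA HyperPrep kit and sequenced in paired-end runs of 75 bp on a NextSeq 500, per the labels. The 15 libraries form 5 groups of 3: growing control, senescent control, senescent with a short hairpin against TXNRD1 (shTXNRD1), senescent with the vehicle DMSO, and senescent with TRi-1, an inhibitor of the TXNRD1 protein. The labels do not give the way senescence was induced, the dose or time of TRi-1, the nature of the control for the hairpin, or whether the 3 replicates of a group were separate cultures. The p-values therefore measure the spread between these samples.

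The deposited table holds counts, whole numbers per Ensembl gene and library, with no scaling: its column totals differ between libraries. The submitters' processing notes name RSEM 1.2.3, DESeq2 without a version, and the builds hg19 and mm10, without saying which step used which. Under RSEM the counts would be rounded estimates, which no source states. The aligner, the gene annotation, the strand used in counting and the treatment of reads shared between similar genes are not given in the sources used here. No genome coordinates are given, since the annotation at hand was of another build (GRCh38). Of 57736 genes in the table, 52301 received a symbol by identifier, 51959 from a table of gene names and the rest from the GENCODE annotation, and genes without a symbol held 0.680% of all counts. In 26318 genes every library was at 0. No gene of the mitochondrial chromosome was in the table.

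Counts were scaled by TMM and fitted with the edgeR 4.0.16 quasi-likelihood F test (robust) in R 4.3.3. A single model covered all 15 libraries, with a coefficient per group, no other term and 10 residual degrees of freedom. The filter of edgeR (filterByExpr, by group) left 15994 genes. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from the fitted model. Levels are TMM-scaled CPM (the usual edgeR unit, a gene's share of the scaled library total), as mean and standard deviation (SD) of the 3 libraries of a group. The 5 comparisons were senescent against growing control, shTXNRD1 against senescent control, TRi-1 against DMSO, the difference between those last effects, and senescent DMSO against senescent control.

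Where a group had no count for a gene, the fold was given as a lower bound against a floor of 3 counts over the group. Intervals and floors cover counting error only. Totals were 18033076 to 28909046 counts per library (median 21156213). With 3 libraries against 3, an exact permutation test on a single gene cannot go below p = 0.1, so the tests rest on a spread shared across genes. On simulated data made from these libraries, the fit recovered 92% to 100% of 4-fold changes, 78% to 84% of 2-fold changes and 50% to 59% of 1.5-fold changes, with at most 5 false calls per comparison. The simulation changed a small set of genes and drew genes independently, without a spread shared between them. Its false calls are therefore no error rate for the real comparisons.

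In all, 30 gene lists were written down, 8 of them as first-tier lists; the mitochondrially encoded genes were not in the table, and CCL3, MMP12, IKBKE, UHRF1, TXNIP, H3C10, H4C14, H2BC8 and PECAM1 had no matching gene. Each list was described by its members called higher or lower, by the same counts adjusted over the list alone, and by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives for the set test were camera with an estimated correlation and fry. Named genes followed a rule: a panel of 12 genes, the 4 largest changes each way among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the 2 members with the smallest p in each first-tier list, and 2 members for up to 4 further lists. For the difference between the inhibitions and for DMSO against control, the largest changes alone were named. The condition on overlap was not applied to the difference between the inhibitions. Not every gene chosen by the rule is printed, and the counts of named genes cover all of them. The comparisons, lists, rule and main tests were chosen before the data were examined.

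Overlaps of called genes were set against the product of their shares and tested with Fisher's exact test. The senescence and shTXNRD1 comparisons share the senescent control libraries, so 20 sets of unchanged shTXNRD1 libraries were simulated against the same controls. Other settings fixed beforehand were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile), no filter, a filter at a mean CPM of 5, genes above 1% of the counts of any library left out, a term for replicate number, the compared groups alone, a 2-fold minimum and each library of the compared groups left out in turn (for overlaps, each of the 15). After the data were seen, 3 more were added: a correction of each library for transcript GC content in 40 bins (a GC value was at hand for 96.5% of tested genes), leaving out 3 libraries at the low-GC end of their groups, and the senescent control as the control of TRi-1. The GC correction used deviations from each gene's mean over all 15 libraries. It therefore also removes any real difference between groups that follows GC content, and cannot part it from a technical bias. No library was left out of the main results.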

Results

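RNA was sequenced from growing and senescent IMR90 fibroblasts, with TXNRD1 inhibited in senescent cells in 2 ways, as part of a study of TXNRD1 and innate immune signalling in senescence. TXNRD1 is the cytosolic thioredoxin reductase, which keeps thioredoxin in its reduced state. The 5 groups of 3 libraries were growing control, senescent control, senescent shTXNRD1, senescent DMSO and senescent TRi-1. Totals ran from 18033076 counts (shTXNRD1 replicate 1) to 28909046 (DMSO replicate 3). The growing libraries held 25484005, 24323413 and 21187297 counts and the senescent control libraries 25246314, 20710735 and 20586451. The other shTXNRD1 libraries held 21156213 and 19066197, the other DMSO libraries 20208075 and 19864361, and the TRi-1 libraries 19811736, 21902533 and 23869302. Levels below are CPM, as mean ± SD with n = 3 libraries, and changes are log2 fold changes ± SE with p-values adjusted by Benjamini-Hochberg from edgeR.

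Senescent control cells were set against growing control cells to show what differed with senescence. The way senescence was induced is not given. Changes of the senescent state therefore cannot be told apart from direct effects of the inducing treatment. Several interleukin and chemokine transcripts rose: CXCL8, a neutrophil attractant, went from 21.7 ± 3.67 to 9949 ± 368 CPM, 458-fold higher, and IL6, a cytokine of the acute-phase response, from 8.11 ± 0.406 to 693 ± 25.3 CPM, 85.3-fold higher. IL1A rose from 4 counts over the growing libraries to 345 ± 14.7 CPM, and IL1B from 10 counts to 2733 ± 133 CPM. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 5.05-fold to 1715 ± 69.7 CPM. LMNB1, the lamin B1 gene, fell 9.81-fold from 57.8 ± 4.02 to 5.88 ± 0.293 CPM. TXNRD1 (ENSG00000198431) itself fell 3.18-fold, from 1635 ± 130 to 515 ± 12 CPM (log2 change -1.67 ± 0.07, adjusted p = 1.12e-10).

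Of 15994 genes tested, 4383 were higher and 4725 lower in senescent cells. The 40 named genes that were tested were all called, and their libraries did not overlap between the groups; the naming rule selects in part for this. CSF3, a granulocyte growth factor, CST1, a cystatin with paralogs of similar sequence, and the chemokine CCL20 had 0 counts in growing cells. They were at least 4171-fold, 1580-fold and 1294-fold higher in senescent cells, against a floor of 3 counts over the growing group. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest falls were in ID2, an inhibitor of differentiation (-4.77 ± 0.16), the glypican GPC6 (-3.79 ± 0.11), STXBP6 (-3.62 ± 0.16) and COLGALT2 (-3.43 ± 0.12). Among the innate sensing genes, STING1, the adaptor of cytosolic DNA sensing, rose from 22.1 ± 2.37 to 56.5 ± 2.66 CPM, while the DNA sensor CGAS fell by 0.61 on the log2 scale (adjusted p = 0.000849). IFNB1, the gene of interferon beta, had 0 counts in all 15 libraries. CDKN2A, which encodes p16 and ARF from shared exons, was lower (-0.54 ± 0.08, adjusted p = 8.99e-05). HRAS, a RAS family proto-oncogene, rose from 14.4 ± 6.27 to 92.7 ± 14.7 CPM (2.70 ± 0.38, adjusted p = 5.75e-05).

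The secretory and inflammatory lists rose. Of 24 measured inflammatory factors of the secretory phenotype, 23 rose and 1 fell (camera, adjusted p = 8.01e-18). Of 25 secreted proteases and their partners, 20 rose and 3 fell (adjusted p = 8.36e-09). The collagenase MMP1 rose 205-fold and the stromelysin MMP3 122-fold. Of 28 NF-kB targets, 23 rose and 3 fell (adjusted p = 1.44e-09), with PTGS2, the inducible cyclooxygenase, 478-fold and IRAK2 8.67-fold higher. Cell cycle genes fell: 33 of 34 S-phase genes (adjusted p = 1.6e-16) and 36 of 36 mitosis genes (adjusted p = 3.51e-25). TYMS, the thymidylate synthase, and the replication helicase subunit MCM3 changed by -1.81 and -1.82 on the log2 scale. The proliferation marker MKI67 fell by 2.81 on the log2 scale and the mitotic kinesin KIF20A fell 8.64-fold. Among 27 p53 targets, 15 rose and 1 fell (adjusted p = 0.000579), with the death receptor TNFRSF10A at 2.36 and the repair gene DDB2 at 1.53. Among 31 NRF2 targets, which serve the antioxidant response, 4 rose and 21 fell (adjusted p = 0.000204). NQO1, a quinone reductase, changed by -2.56, and SLC7A11, the cystine transporter, by -2.87. Interferon-stimulated genes split, with 6 of 36 higher and 17 lower (adjusted p = 0.117). CXCL10 rose 29.6-fold and IFIT1 fell 3.98-fold, and the median of this list was -0.30 against a mean of 0.08. Adjusted over the list alone, these counts were the same except for NRF2 targets, with 4 higher and 22 lower.

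Of the further lists, 17 of 22 RAS-MAPK feedback genes rose and 1 fell (adjusted p = 1.76e-07), including DUSP4 (29.6-fold) and SPRY4 (3.88-fold). Of 25 glycolysis genes 18 rose and none fell (adjusted p = 1.31e-07; 19 adjusted over the list alone), with HK2 4.05-fold and ENO2 5.66-fold higher. Of 10 replication histone genes 9 rose (adjusted p = 5.38e-05), with H2BC21 3.35-fold and H4C8 3.18-fold higher, though histone genes share sequence. Cytosolic ribosomal protein genes fell in 24 of 38 (adjusted p = 2.05e-05), with RPS23 at -0.85 and RPL4 at -0.62. Cholesterol synthesis rose in 12 of 19 and fell in 1 (adjusted p = 0.00202), and lysosomal genes rose in 17 of 25 and fell in 3 (adjusted p = 0.000164; 19 and 3 adjusted over the list alone). ATF4 targets rose in 4 and fell in 20 of 27 (adjusted p = 0.000134), and metallothioneins rose in 4 of 5 (adjusted p = 0.0108). The thioredoxin and glutathione list had 6 higher and 16 lower of 34 (adjusted p = 0.0275), a call lost at adjusted p = 0.141 with an estimated correlation. Collagen and matrix genes had 13 higher and 4 lower of 31 (adjusted p = 0.0195), lost at adjusted p = 0.23 with an estimated correlation.

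Lists that missed the threshold were arrest and chromatin genes (5 higher and 12 lower of 20, adjusted p = 0.0656), nucleic acid sensing (7 and 6 of 16, adjusted p = 0.871), selenoproteins (3 and 2 of 18, adjusted p = 0.715) and heat shock (2 and 11 of 21, adjusted p = 0.0656). The others were endoplasmic reticulum stress (2 and 6 of 18, adjusted p = 0.64), contractile and TGF-beta genes (4 and 11 of 19, adjusted p = 0.0656), nuclear-encoded oxidative phosphorylation (0 and 15 of 34, adjusted p = 0.0654) and MHC class I presentation (7 and 3 of 15, adjusted p = 0.121). After the GC correction contractile (adjusted p = 0.0135), arrest (0.0279), heat shock (0.0336) and oxidative phosphorylation genes (0.0373) were called lower. Without growing control replicate 1 contractile (0.0263), arrest (0.0345) and oxidative phosphorylation genes (0.0490) were called, and the last also without senescent control replicate 1 (0.0456). Markers of other cell types also moved: 5 of 6 endothelial markers rose (adjusted p = 0.0187) and 4 of 6 leukocyte markers rose (adjusted p = 0.0345), while 2 of 6 epithelial markers rose and 2 fell (adjusted p = 0.901). The leukocyte call was lost at adjusted p = 0.0874 with an estimated correlation and at 0.0509 without growing control replicate 2, or 0.0525 without the 3 libraries at the low-GC end of their groups. Across genes, which are not independent replicates, the senescence changes had a Spearman correlation of 0.278 with transcript GC content. Median and mean differed in sign for the epithelial, selenoprotein and endoplasmic reticulum lists. Adjusted over the list alone, counts of the lists in this paragraph differed for arrest (6 and 12), sensing (8 and 6), reticulum stress (2 and 5) and contractile genes (5 and 11).

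**Figure D1:**
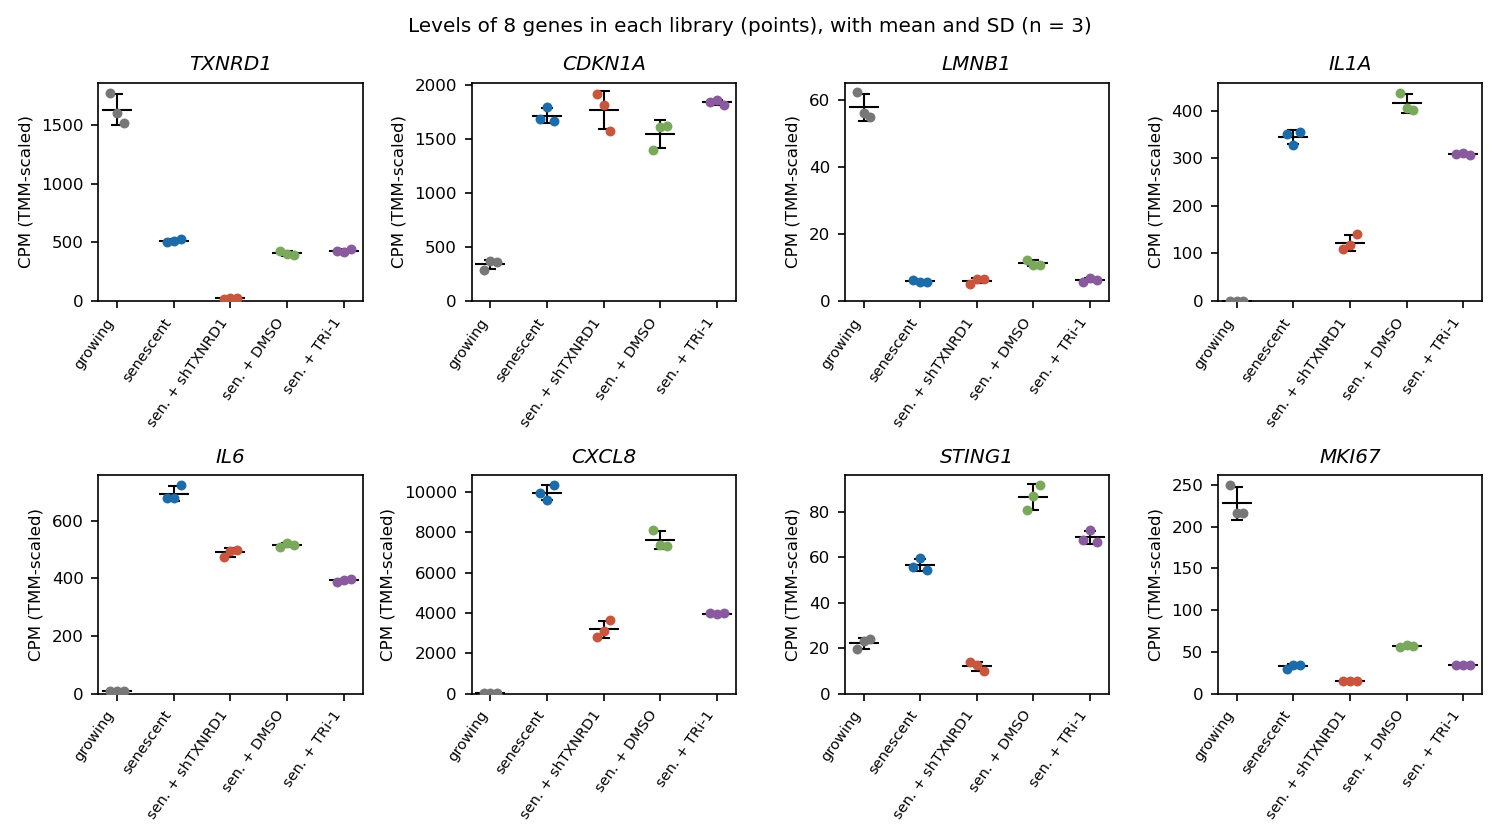
Levels of 8 genes in each library, in TMM-scaled CPM on linear axes that start at 0, by group; points are libraries and bars give the mean and SD of 3 libraries. TXNRD1 stood at 22.6 CPM with the hairpin against 515 CPM in the senescent control, and at 431 CPM with TRi-1 against 408 CPM with DMSO.

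The hairpin comparison, shTXNRD1 against senescent control, asked what the hairpin against TXNRD1 did in senescent cells. With a single hairpin condition, effects of TXNRD1 loss cannot be told apart from other effects of the hairpin. TXNRD1 fell 22.7-fold, from 515 ± 12 to 22.6 ± 2.30 CPM (-4.51 ± 0.08, adjusted p = 2.02e-13). STING1 fell 4.68-fold, from 56.5 ± 2.66 to 12.1 ± 1.98 CPM, and CXCL8 fell 3.12-fold, from 9949 ± 368 to 3194 ± 423 CPM. IL1A (-1.49 ± 0.08), IL1B (-0.92 ± 0.06) and IL6 (-0.50 ± 0.05) fell as well. CDKN1A stood at 0.04 ± 0.09 (adjusted p = 0.744), LMNB1 at 0.05 ± 0.11 (adjusted p = 0.755) and CGAS at -0.13 ± 0.13 (adjusted p = 0.438), none past the threshold. After the GC correction CDKN1A was called higher (0.31, adjusted p = 0.00120), as it was without the 3 libraries at the low-GC end (0.12, adjusted p = 0.0266).

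With the hairpin 4134 genes were higher and 3971 lower. Of 42 named genes tested, 39 were called, and their libraries did not overlap between the groups; the naming rule selects in part for this. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises were in the secretogranin SCG2 (3.98 ± 0.16), the junction proteins F11R (2.82 ± 0.15) and CXADR (2.70 ± 0.10), and the OX40 ligand TNFSF4 (2.64 ± 0.10). By the same limits the largest falls beside TXNRD1 were in the protease inhibitors SERPINB4 (-6.02 ± 0.18), which has the close paralog SERPINB3, and SERPINA9 (-4.69 ± 0.11), and in RAB43 (-4.31 ± 1.01). RAB43 levels were widely spread, at 8.04 ± 2.84 against 0.413 ± 0.336 CPM. Its call was lost in limma-voom (adjusted p = 0.0915), and its change was -4.94 without shTXNRD1 replicate 1. CDKN2A rose (0.83 ± 0.08, adjusted p = 1.95e-06). HRAS was lower (-0.92 ± 0.35, adjusted p = 0.0454). That call was lost without senescent control replicate 1 (adjusted p = 0.0942) or 2 (0.127) and without shTXNRD1 replicate 2 (0.0983) or 3 (0.121). It was also lost with a replicate term (0.0700), upper-quartile scaling (0.0568), no filter (0.126) and the compared groups alone (0.144).

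The lists that rose with senescence fell with the hairpin in several cases. Inflammatory factors had 3 higher and 18 lower of 24 (adjusted p = 2.17e-06), and 3 and 19 adjusted over the list alone. This call was lost at adjusted p = 0.0544 with an estimated correlation. INHBA, an activin subunit, changed by -1.50 and the chemokine CXCL6 by -2.12. Secreted proteases had 1 higher and 18 lower of 25 (adjusted p = 3.12e-06; 1 and 20 adjusted over the list alone), with IGFBP5 at -1.45 and the plasminogen activator PLAT at -1.37. NF-kB targets had 2 higher and 19 lower of 28 (adjusted p = 7.05e-06; the same adjusted over the list alone). IRF1, an interferon regulatory factor, changed by -2.22 and BIRC3, an apoptosis inhibitor, by -2.56. Interferon-stimulated genes had 7 higher and 16 lower of 36 (adjusted p = 0.0437; 8 and 17 adjusted over the list alone), with CXCL10 at -2.70 and SAMD9L at -1.30. The interferon call was lost at adjusted p = 0.183 with an estimated correlation, and without shTXNRD1 replicate 1 (0.0576), 2 (0.0539) or 3 (0.0603), or all 3 low-GC libraries (0.0636).

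Cell cycle genes, already low, fell further. S-phase genes had 3 higher and 21 lower of 34 (adjusted p = 0.00453; 3 and 22 adjusted over the list alone), with CDC6 at -1.61 and RRM2 at -1.12. Mitosis genes had 1 higher and 24 lower of 36 (adjusted p = 7.72e-06; 1 and 25 adjusted over the list alone), with BIRC5 at -2.35 and MKI67 at -1.14. The mitosis call was lost at adjusted p = 0.183 with an estimated correlation. Among p53 targets 14 of 27 rose and 2 fell (adjusted p = 0.000572; the same adjusted over the list alone), with TNFRSF10B at 0.79 and TP53INP1 at 1.18. This call was lost at adjusted p = 0.0544 with an estimated correlation. NRF2 targets had 4 higher and 11 lower of 31 (adjusted p = 0.0437; the same adjusted over the list alone). The transporter ABCC3 changed by -1.72 while SLC7A11 rose by 1.05. That call was lost at adjusted p = 0.183 with an estimated correlation, at 0.0677 without shTXNRD1 replicate 3, at 0.0980 after the GC correction and at 0.0567 without the 3 low-GC libraries.

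Cholesterol synthesis fell in 17 of 19 genes (adjusted p = 1e-06), with the isomerase IDI1 at -1.97. Contractile and TGF-beta genes had 1 higher and 17 lower of 19 (adjusted p = 1.12e-06), with the tropomyosin TPM1 at -1.63 and TGFB2 at -1.55. Collagen and matrix genes had 4 higher and 21 lower of 31 (adjusted p = 0.000104), with THBS1 at -1.36 and FBN1 at -1.08. Glycolysis genes had 3 higher and 15 lower of 25 (adjusted p = 0.00377), with HK2 at -1.59 but the glucose transporter SLC2A3 at 1.62. With an estimated correlation the collagen call was lost at adjusted p = 0.126 and the glycolysis call at adjusted p = 0.183. Heat shock genes rose in 11 of 21 and fell in 2 (adjusted p = 0.0432), and oxidative phosphorylation genes rose in 12 of 34 and fell in 1 (adjusted p = 0.0432). These calls were lost at adjusted p = 0.25 and adjusted p = 0.371 with an estimated correlation. Without shTXNRD1 replicate 3 they stood at 0.0522 and 0.0603, and oxidative phosphorylation at 0.0539 without shTXNRD1 replicate 2. Of 6 leukocyte markers 3 fell (adjusted p = 0.0437), lost at adjusted p = 0.149 with an estimated correlation. It was also lost without shTXNRD1 replicate 2 (0.0689) or 3 (0.0677), after the GC correction (0.0809) and without the 3 low-GC libraries (0.0841). Adjusted over the list alone, counts in this paragraph differed for contractile (1 and 18), heat shock (11 and 3), oxidative phosphorylation (11 and 1) and leukocyte genes (0 and 4). The other measured lists missed the threshold, among them nucleic acid sensing (2 higher and 6 lower of 16, adjusted p = 0.166) and thioredoxin and glutathione genes (6 and 10 of 34, adjusted p = 0.223). Across genes, the hairpin changes had a Spearman correlation of -0.312 with transcript GC content.

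The inhibitor comparison, TRi-1 against DMSO in senescent cells, asked what the inhibitor did. With a single compound, effects of inhibiting the protein cannot be told apart from other effects of TRi-1. Among chemokine genes, CXCL6 fell 12.8-fold, from 444 ± 35.8 to 34.6 ± 1.23 CPM, and CXCL8 fell 1.92-fold, from 7603 ± 447 to 3963 ± 40.1 CPM. CXCL5, a neutrophil attractant, changed by -1.46 ± 0.07, and IL1A (-0.43 ± 0.08), IL1B (-0.28 ± 0.06) and IL6 (-0.39 ± 0.05) by less. Matrix genes fell, with periostin, POSTN, at -1.86 ± 0.08. TXNRD1 mRNA stood at 431 ± 11.6 against 408 ± 19.3 CPM (0.08 ± 0.07, adjusted p = 0.483). CDKN1A (0.25 ± 0.09, adjusted p = 0.0753), CGAS (0.15 ± 0.13, adjusted p = 0.481) and HRAS (0.47 ± 0.35, adjusted p = 0.388) missed the threshold. With the compared groups alone CDKN1A (adjusted p = 0.0192) and HRAS (0.0284) were called higher. After the GC correction HRAS (0.21, adjusted p = 0.00402) and TXNRD1 (0.115, adjusted p = 0.00254) were called higher. Without the 3 low-GC libraries CDKN1A (0.19, adjusted p = 0.00454) and TXNRD1 (0.12, adjusted p = 0.0461) were.

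With TRi-1 1222 genes were higher and 1954 lower. The number higher was 781 without DMSO replicate 1, and 793, 799 and 772 without TRi-1 replicates 1, 2 and 3. It was 812 without a filter, 2344 with the compared groups alone, 2582 after the GC correction and 1967 without the 3 libraries at the low-GC end. The number lower was 3037 with the compared groups alone. Of 42 named genes tested, 38 were called, and their libraries did not overlap between the groups; the naming rule selects in part for this. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises were in ENSG00000227844, which has no symbol (1.85 ± 0.23), SH2D5 (1.80 ± 0.19), GPRC5A (1.72 ± 0.08) and the non-coding LINC01705 (1.39 ± 0.21). By the same limits the largest falls were in the fetal globin gene HBG2 (-3.92 ± 0.21), whose reads are hard to part from HBG1, CXCL6 (-3.68 ± 0.10), the complement factor CFB (-3.16 ± 0.17) and PLPPR4 (-2.95 ± 0.14). LMNB1 fell (-0.85 ± 0.10). CDKN2A rose (0.34 ± 0.08, adjusted p = 0.0110), a call lost without DMSO replicate 1 (adjusted p = 0.0554) and after the GC correction (0.663). STING1 was lower (-0.33 ± 0.10, adjusted p = 0.0332). Its call was lost without DMSO replicates 2 (0.0839) and 3 (0.120), without TRi-1 replicates 1 (0.101), 2 (0.0675) and 3 (0.117), and with a replicate term (0.0524).

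Inflammatory factors had 1 higher and 12 lower of 24 (camera, adjusted p = 1.39e-08; 1 and 15 adjusted over the list alone). Interferon-stimulated genes had 0 higher and 15 lower of 36 (adjusted p = 3.72e-06; 0 and 17 adjusted over the list alone), with PLSCR1 at -0.71 and IFI44 at -1.38. Collagen and matrix genes had 0 higher and 21 lower of 31 (adjusted p = 7.05e-16; 0 and 22 adjusted over the list alone), with POSTN at -1.86 and COL12A1 at -1.28. Contractile genes had 1 higher and 11 lower of 19 (adjusted p = 0.000612), with the smooth muscle myosin MYH11 at -2.45 and ANKRD1 at 1.13. Mitosis genes had 0 higher and 26 lower of 36 (adjusted p = 1.31e-11; 0 and 28 adjusted over the list alone), with MKI67 at -0.74 and NUSAP1 at -0.87. The mitosis call was lost at adjusted p = 0.0673 with an estimated correlation. Secreted proteases had 1 higher and 7 lower of 25 (adjusted p = 0.0178; 1 and 8 adjusted over the list alone), lost at adjusted p = 0.236 with an estimated correlation. IGFBP5 changed by -1.07 and PLAT by -0.88. S-phase genes had 0 higher and 2 lower of 34 (adjusted p = 0.763; 0 and 1 adjusted over the list alone), namely MCM6 (-0.45, adjusted p = 0.0114) and MCM3 (-0.23, adjusted p = 0.0213). The MCM6 call was lost without DMSO replicate 1 (0.0509) or TRi-1 replicate 1 (0.0595). The MCM3 call was lost without DMSO replicates 1 (0.0691) and 2 (0.0626), without TRi-1 replicates 2 (0.0808) and 3 (0.0568), and without a filter (0.136).

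NF-kB targets had 5 higher and 5 lower of 28 (adjusted p = 0.778; 5 and 6 adjusted over the list alone), with the adhesion molecule VCAM1 at -1.43 and PTGS2 at -0.81. Among p53 targets 7 of 27 rose (adjusted p = 0.00095; the same adjusted over the list alone), with POLH at 0.77 and TP53I3 at 0.47. This call was lost at adjusted p = 0.063 with an estimated correlation. NRF2 targets had 3 higher and 6 lower of 31 (adjusted p = 0.846; 3 and 7 adjusted over the list alone), with the aldo-keto reductase AKR1C1 at -1.52 and the sulfiredoxin SRXN1 at 0.42. Their median was 0.12 and their mean -0.06. Heat shock genes rose in 9 of 21 (adjusted p = 1.81e-05; 10 adjusted over the list alone), with FKBP4 at 0.44 and STIP1 at 0.28. The STIP1 call was lost after the GC correction (adjusted p = 0.139). Cholesterol synthesis rose in 4 of 19 (adjusted p = 0.00854; 5 higher and 1 lower adjusted over the list alone), with NSDHL at 0.43. MHC class I genes fell in 7 of 15 (adjusted p = 0.0196; 1 higher and 9 lower adjusted over the list alone), lost at adjusted p = 0.357 with an estimated correlation and at 0.0502 without DMSO replicate 3. Metallothioneins had 2 of 5 higher (adjusted p = 0.0414), lost at adjusted p = 0.108 with an estimated correlation and at 0.0560 without TRi-1 replicate 2. Thioredoxin and glutathione genes had 6 higher and 4 lower of 34 (adjusted p = 0.0448), lost at adjusted p = 0.236 with an estimated correlation. It was also lost without DMSO replicates 2 (0.0625) and 3 (0.0594) or TRi-1 replicates 2 (0.0560) and 3 (0.0590). Cytosolic ribosomal protein genes passed the set test (adjusted p = 0.0448) with 0 of 38 members called, lost at adjusted p = 0.385 with an estimated correlation. The ribosomal call was also lost without DMSO replicate 3 (0.0697), without TRi-1 replicates 2 (0.0560) and 3 (0.0867), and after the GC correction (0.0767). Nucleic acid sensing had 0 higher and 3 lower of 16 (adjusted p = 0.905; 2 and 3 adjusted over the list alone), and its median was 0.04 against a mean of -0.08. Across genes, the TRi-1 changes had a Spearman correlation of 0.323 with transcript GC content.

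With the senescent control in place of DMSO, an alternative added after the data were seen, TRi-1 turned the direction of several genes. LMNB1 stood at 0.08, STING1 at 0.28, PLAT at 0.22, MKI67 at 0.08, TXNRD1 at -0.26 (adjusted p = 0.0260), CGAS at -0.19, NSDHL at -0.17, ENSG00000227844 at -0.25 and TP53I3 at -0.0055. Calls for IL1A (adjusted p = 0.217), SH2D5 (0.608), NUSAP1 (0.178), POLH (0.110), ANKRD1 (0.0602), MCM6 (0.297) and MCM3 (0.130) were lost. Mitosis genes then had 5 higher and 0 lower (adjusted p = 0.0880), proteases 5 and 4 (adjusted p = 0.403), and cholesterol synthesis 0 and 14 (adjusted p = 1.00e-10, lower). The heat shock (adjusted p = 0.0884), p53 (0.0597), metallothionein (0.360) and thioredoxin (0.326) list calls were lost, and NRF2 (0.00125) and NF-kB targets (0.00783) were called lower. Further lists gained a call against this control, namely RAS-MAPK feedback (1.97e-06, higher), oxidative phosphorylation (0.00101, higher), glycolysis (0.0223, higher), ATF4 targets (0.00239, lower) and selenoproteins (0.00918, lower). With an estimated correlation the NRF2 (adjusted p = 0.0509), oxidative phosphorylation (adjusted p = 0.176), glycolysis (adjusted p = 0.284) and selenoprotein calls (adjusted p = 0.0539) were lost. Against this control CXCL6 changed by -3.30, CXCL8 by -1.33, CFB by -2.47, PLPPR4 by -2.28, AKR1C1 by -2.12, VCAM1 by -1.83, POSTN by -0.99 and COL12A1 by -0.83. GPRC5A rose by 0.40 (adjusted p = 0.00207) and CDKN2A by 1.01, and SH2D5 stood at 0.16. Against both controls 825 genes were lower with TRi-1 and 341 higher, including 10 inflammatory factors, 10 interferon-stimulated genes and 15 matrix genes among the lower. Another 98 genes were called in opposite directions against the controls. The same TRi-1 libraries enter both comparisons, so these calls are not independent.

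**Figure D2:**
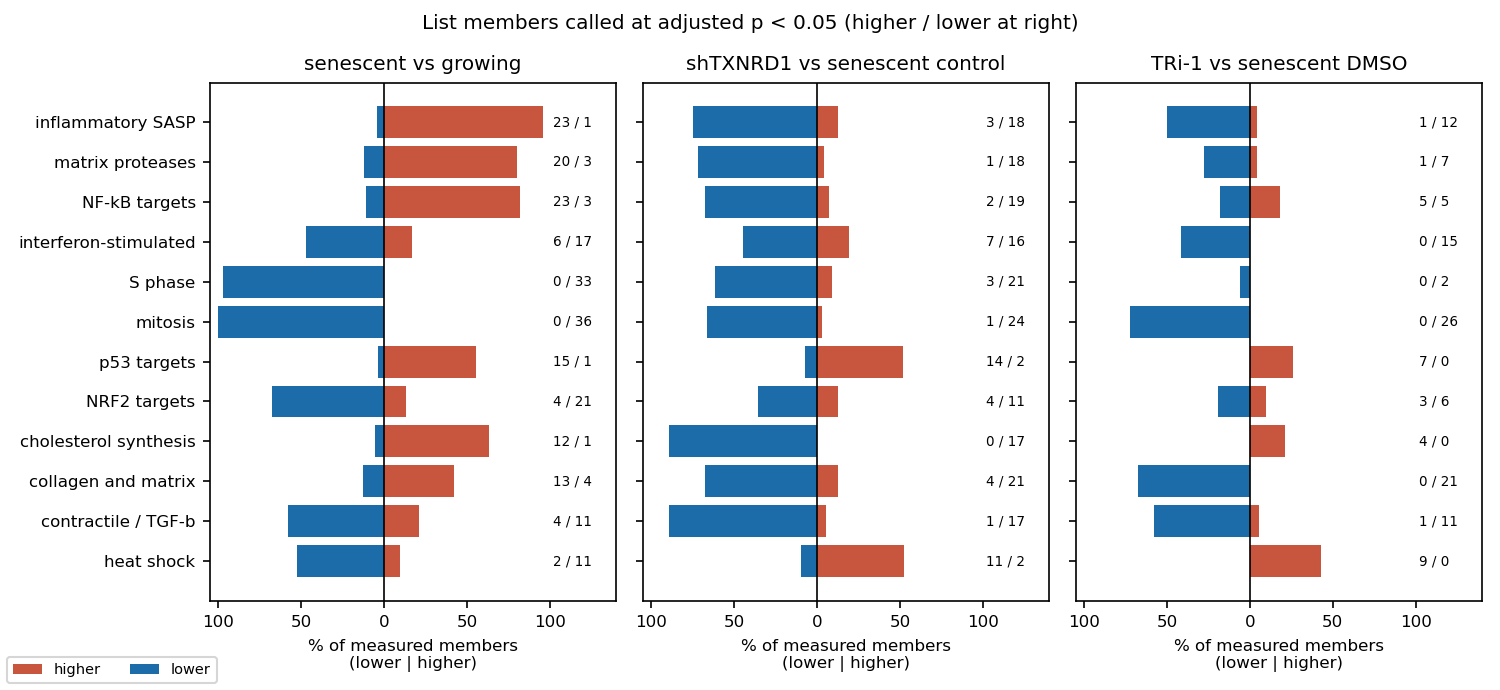
Share of the measured members of 12 gene lists called higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, in percent of measured members, for 3 comparisons, with the counts higher and lower at the right of each panel. Inflammatory factors were called higher in 23 of 24 with senescence, and lower in 18 with shTXNRD1 and 12 with TRi-1.

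The hairpin and the inhibitor were then set side by side, each against its own control, with no library in common. The chemokine genes CXCL8 (by 1.64 and 0.94 on the log2 scale) and CXCL6 (by 2.12 and 3.68) fell with each. Both lowered 868 genes, against 485 expected from independent calls (Fisher's exact test, p = 2.13e-91), and both raised 435, against 316 expected (p = 4.06e-15). Opposite calls were made for 851 genes. The TRi-1 calls depend in part on the DMSO control. Of 1954 genes lower with TRi-1, 825 were also lower against the senescent control, and 341 of 1222 were also higher. Overlaps with the hairpin were not counted for TRi-1 against that control. Genes are not independent replicates, and across all genes the effects had a Pearson correlation of 0.0882 and a Spearman correlation of 0.0174. After the GC correction these were 0.147 and 0.134.

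The test of the difference called 3538 genes with a higher and 3124 with a lower effect of the hairpin than of TRi-1. Among called genes with a mean log2 CPM of at least 1, the largest positive differences were in the growth factor BMP5 (4.10 ± 0.16), SCG2 (3.90 ± 0.23), F11R (3.19 ± 0.21) and PLPPR4 (3.04 ± 0.18). By the same limits the largest negative differences were in SERPINB4 (-5.02 ± 0.23), TXNRD1 (-4.59 ± 0.11), RAB43 (-4.40 ± 1.24, lost in limma-voom at adjusted p = 0.0764, and -5.03 without shTXNRD1 replicate 1) and SERPINA9 (-3.86 ± 0.14). Cholesterol synthesis genes had the lower effect with the hairpin in 16 of 19 (camera, adjusted p = 9.53e-08), and NF-kB targets in 19 of 28 with 3 the other way (adjusted p = 0.000114). Adjusted over the list alone, the NF-kB counts were 19 and 4. The number raised by both was 281 without DMSO replicate 3, 285 without TRi-1 replicate 3, 271 without a filter, 1061 after the GC correction (741 expected) and 780 without the 3 low-GC libraries. The number lowered by both was 1490 after the GC correction (895 expected). The number of opposite calls was 525 without DMSO replicate 1, 560 and 562 without TRi-1 replicates 1 and 2, and 1611 after the GC correction.

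The senescence changes were compared with each inhibition to ask whether inhibition acted on the genes that senescence changed. CXCL8, IL6, IL1A and IL1B were among 373 genes that rose with senescence and fell with both inhibitions. Conversely, 138 genes that fell with senescence rose with both. In the same direction throughout, 322 genes fell with senescence and with both inhibitions, and 161 rose. Counts expected from independent calls were not computed for these groups of genes. Of the genes that rose with senescence, 1499 fell with shTXNRD1, against 1088 expected (Fisher's exact test, p = 3.69e-61). Of those that fell, 1622 rose, against 1221 expected (exact p = 7.2e-55). In the same direction as senescence, the hairpin raised 1003 genes, against 1133 expected (exact p = 1.24e-07). It lowered 1225 that senescence lowered, against 1173 expected (exact p = 0.0388). These comparisons share the senescent control libraries. The covariance across genes was -0.253, against a mean of -0.0467 in 20 simulations without a hairpin effect. Genes were simulated independently, so a GC bias shared by the genes of a library was left out. The senescence and hairpin changes correlated with GC content in opposite directions (Spearman 0.278 and -0.312), which by itself makes the covariance more negative. The simulations thus account for the shared controls but not for GC content. With TRi-1, 665 genes that rose with senescence fell, against 535 expected (exact p = 6.8e-12). A further 350 that fell with senescence rose, against 361 expected (exact p = 0.493). TRi-1 also lowered 823 genes that senescence lowered, against 577 expected (exact p = 1.13e-36), and raised 471 that senescence raised, against 335 expected (exact p = 1.47e-18). The senescence and TRi-1 changes both correlated positively with GC content (Spearman 0.278 and 0.323), so a GC bias would by itself favour calls in the same direction. The counts of 823 and 471 were not repeated after the GC correction. The count of 350 was 229 without TRi-1 replicate 1, 230 without TRi-1 replicate 3, 200 without a filter, 942 after the GC correction (861 expected) and 659 without the 3 low-GC libraries. The count of 665 was 1162 after the GC correction (940 expected).

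Senescent DMSO and senescent control cells, the controls of the inhibitions, were compared with each other. Mitosis genes were higher with DMSO in 29 of 36 (camera, adjusted p = 1.85e-18), and MKI67 stood at 57.2 ± 0.865 against 32.5 ± 2.35 CPM. Cholesterol synthesis genes were lower in 16 of 19 (adjusted p = 4.02e-18). RAS-MAPK feedback genes were higher in 11 of 22 and lower in 1 (adjusted p = 4.01e-06), and NRF2 targets lower in 9 of 31 (adjusted p = 0.000226). Adjusted over the list alone, 32 mitosis genes were higher, 18 cholesterol genes lower, and 2 NRF2 targets higher and 12 lower. Proteases (8 higher and 1 lower of 25, adjusted p = 0.00258) and arrest and chromatin genes (6 and 1 of 20, adjusted p = 0.00514) were higher with DMSO, as were contractile genes (6 and 1 of 19, adjusted p = 0.0360). Lower were heat shock genes (0 and 5 of 21, adjusted p = 0.00514), selenoproteins (0 and 5 of 18, adjusted p = 0.00631) and ATF4 targets (1 and 6 of 27, adjusted p = 0.0275). Interferon-stimulated genes (1 and 9 of 36) and NF-kB targets (3 and 8 of 28) were also lower (adjusted p = 0.0360 for each). Adjusted over the list alone, these counts were 10 and 1 for proteases, 8 and 1 for arrest and chromatin genes, 0 and 6 for selenoproteins, 1 and 8 for ATF4 targets, 2 and 10 for interferon-stimulated genes and 5 and 9 for NF-kB targets. With an estimated correlation the calls for proteases (adjusted p = 0.128), heat shock genes (0.128), interferon-stimulated genes (0.128), contractile genes (0.122), NF-kB targets (0.0750), ATF4 targets (0.0600) and selenoproteins (0.0546) were lost. The interferon call was also lost without senescent control replicate 3 (0.0636), DMSO replicates 1 (0.0825) and 2 (0.0574), and the 3 low-GC libraries (0.0626). The NF-kB call was lost without senescent control replicate 2 (0.0609), DMSO replicate 1 (0.0748) and the 3 low-GC libraries (0.0567). The contractile call was lost without DMSO replicates 2 (0.0574) and 3 (0.0515) and with the compared groups alone (0.0562). The ATF4 call was lost with the compared groups alone (0.0607) and after the GC correction (0.0548). Cytosolic ribosomal protein genes (adjusted p = 0.0655) gained a call with the compared groups alone (0.0102), without senescent control replicate 1 (0.0378), after the GC correction (0.0362) and without the 3 low-GC libraries (0.0163). Collagen and matrix genes gained one after the GC correction (0.0483) and without the 3 low-GC libraries (0.0421), and oxidative phosphorylation genes with the compared groups alone (0.0390). In all, 1337 genes were higher and 1258 lower. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises were in LRFN5 (2.14 ± 0.15), the non-coding MIAT (1.91 ± 0.10) and RASL12 (1.91 ± 0.16), and the largest falls in ENSG00000227844 (-2.10 ± 0.23), the cornified envelope protein IVL (-2.05 ± 0.14) and the natriuretic peptide receptor NPR3 (-1.86 ± 0.20). The number higher was 2229 with the compared groups alone and 2695 after the GC correction. The number lower was 2572 after the GC correction and 2028 without the 3 low-GC libraries.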

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

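The tests of TRi-1 against the senescent control were chosen after the results were seen; the tests of the difference and the splits of the samples were planned. The effects of the hairpin and of TRi-1, each against its own control, differed in edgeR's test of the difference for 8 panel genes. The hairpin effect minus the TRi-1 effect was -4.59 for TXNRD1, -1.90 for STING1, -1.39 for HRAS, -1.06 for IL1A, -0.70 for CXCL8, -0.64 for IL1B, 0.49 for CDKN2A and 0.90 for LMNB1. HRAS had the weakest evidence of these (adjusted p = 0.0397). The control groups themselves differed, so each of these differences also holds the gap between DMSO and senescent control. Against the senescent control TRi-1 changed CDKN2A by 1.01 and the hairpin by 0.83, an order opposite to the difference above that was not tested itself, and LMNB1 stood at 0.08 and STING1 at 0.28.

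For 6 gene lists the effects differed by camera. The median difference was -0.95 for cholesterol synthesis (adjusted p = 9.53e-08), -0.83 for NF-kB targets (0.000114), -0.56 for glycolysis (0.000922), -0.34 for secreted proteases (0.00365), -0.60 for contractile and TGF-beta genes (0.00472) and -0.30 for thioredoxin and glutathione genes (0.0294). With an estimated correlation only cholesterol synthesis (adjusted p = 0.00219) and NF-kB targets (adjusted p = 0.00738) remained past the threshold among these 6. Both differences also hold the gap between the controls. Cholesterol synthesis genes were lower with DMSO than in the senescent control in 16 of 19, and against the senescent control TRi-1 lowered 14 of 19 (median -0.50), the direction of the hairpin. NF-kB targets were also lower with TRi-1 against that control (adjusted p = 0.00783). The thioredoxin call was lost without shTXNRD1 replicate 1 (0.0506). With each library of the compared groups left out in turn, 5 to 8 lists were called with the lower effect for the hairpin. The hairpin and TRi-1 moved 851 genes in opposite directions, and 525 without DMSO replicate 1, 560 without TRi-1 replicate 1 and 562 without TRi-1 replicate 2. Independent calls would give nearly as many as the 851. With the hairpin higher and TRi-1 lower there were 528, against 505 expected, and the other way 323, against 303 expected.

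Other splits of the same libraries were counted for each comparison. Of 100 splits drawn for the difference between the inhibitions, 1, the real one, called as many as 6662 genes. The count follows the hairpin contrast, which splits that leave it whole keep for the most part, so it is no test of whether the inhibitions differ and does not settle whether chance can be excluded for that. The highest of the others, with TRi-1 and DMSO labels exchanged, called 6499. The 11 other splits that kept shTXNRD1 and control libraries together called 3974 to 6499 genes and the 88 that mixed them at most 382. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each, 1 split called as many genes as the real one, itself: 9108 with senescence, 8105 with the hairpin, 3176 with TRi-1 and 2595 with DMSO, and the highest other split called 0 in edgeR.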

How the results depend on the processing

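The GC correction, the removal of 3 low-GC libraries and the other control for TRi-1 were tests chosen after the results were seen; the other alternatives were planned. Of 138 results for named genes, 112 kept direction and side of the threshold under every alternative run; of 2427 alternative values 2372 did so, 34 lost the call, 8 gained it and 13 changed sign. Lists past the threshold under neither setting were given no direction, and genes without an adjusted p in DESeq2 were left out there. DESeq2, limma-voom, RLE and upper-quartile scaling, the filter at a mean CPM of 5 and the removal of dominant genes moved no count of called genes by over 1.5 times. Replicate numbers did not pair the libraries, and a term for them left 2743 genes called for TRi-1 against DMSO. Where no cause is named below, the cause was not tested. In data simulated at this depth, number of libraries and spread of each gene, 50% to 59% of 1.5-fold changes were recovered. A spread shared between genes was not simulated, and which of these limits recovery was not tested.

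Without a filter, more genes were tested; TRi-1 had 812 genes higher, both inhibitions raised 271, and 200 were lower with senescence and higher with TRi-1. With the compared groups alone TRi-1 had 2344 higher and 3037 lower, and DMSO 2229 higher. After the GC correction 10 lists fell with senescence, TRi-1 had 2582 genes higher, DMSO had 2695 higher and 2572 lower, both inhibitions lowered 1490 and raised 1061, and 1611 were opposite. There, 1162 genes rose with senescence and fell with TRi-1 and 942 did the reverse. Without the 3 low-GC libraries 10 lists fell with senescence, TRi-1 had 1967 higher, DMSO 2028 lower, both raised 780, 659 fell with senescence and rose with TRi-1, and LMNB1 with the hairpin stood at -0.0014. With the senescent control as control of TRi-1, TXNRD1 stood at -0.26, LMNB1 0.0813, CGAS -0.19, STING1 0.28, ENSG00000227844 -0.25, PLAT 0.22, MKI67 0.0782, TP53I3 -0.0055 and NSDHL -0.17. Its set tests turned for cholesterol synthesis (adjusted p = 1.00e-10), proteases (0.403), mitosis (0.0880) and NRF2 targets (0.00125; adjusted p = 0.0509 with an estimated correlation).

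A 2-fold minimum, stricter by construction, left 2142 higher and 1249 lower with senescence, 724 and 1430 with the hairpin, 65 and 318 with TRi-1, 953 and 1261 for their difference, 149 and 134 for DMSO, 143 lowered and 16 raised by both inhibitions, and 20 opposite. With an estimated correlation, lists called higher and lower were 0 and 5 for the hairpin and 2 and 4 for TRi-1, 2 lower for the difference, and 3 and 2 for DMSO. With fry, 11 lists were lower with senescence, 5 higher and 20 lower with the hairpin, 13 lower with TRi-1, 3 higher and 15 lower for the difference, and 13 lower for DMSO. Leaving out in turn each library of the compared groups, which leaves fewer samples, gave 772 to 845 genes higher with TRi-1 in place of 1222. For overlaps, leaving out each of the 15 libraries gave 525 to 1093 opposite calls, 281 to 530 raised by both, and 229 to 456 lower with senescence and higher with TRi-1. Lists called higher ran from 1 to 3 for the hairpin and 3 to 6 for TRi-1. With the hairpin CDKN1A ran from -0.0307 to 0.115 and LMNB1 from -0.0202 to 0.139, neither of them called; CDKN1A was called at 0.31 after the GC correction (adjusted p = 0.00120).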

Other observations

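All tests in this part on GC content, replicate numbers, depth and globins were chosen after the results were seen. For the share of growing cells the prediction was written before its value was computed. That test addresses the higher mitosis genes with DMSO, a pattern found in the results. The genes in these first paragraphs were chosen after their values were seen. Some genes with 0 or 1 counts over the growing libraries were expressed in senescent cells. No list was tested for them, and of 6 epithelial markers fixed before the data were seen 2 rose and 2 fell (adjusted p = 0.901). The cornified envelope gene LCE1F stood at 19.0 ± 1.52 CPM (SD, n = 3) in the senescent control and at 0 counts in growing cells, and IVL at 11.9 ± 0.614 CPM and 0 counts. The epithelial transcription factor EHF stood at 101 ± 2.99 CPM against 1 count over the growing libraries, the elastase inhibitor PI3 at 12.5 ± 0.873 CPM and SERPINB4 at 33.2 ± 0.296 CPM, both against 0 counts. With the hairpin SERPINB4 fell to 0.504 ± 0.229 CPM and PI3 to 4.06 ± 0.348 CPM, while LCE1F stood at 18.8 ± 1.37 CPM (log2 change -0.02, adjusted p = 0.92 in edgeR, and 0.76, adjusted p = 0.0701, after GC correction) and EHF rose to 130 ± 12.8 CPM. The acute-phase gene SAA1 stood at 24.8 ± 2.08 CPM in the senescent control, 7.89 ± 0.485 with the hairpin, 27.6 ± 1.92 with DMSO and 6.08 ± 0.151 with TRi-1.

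Some genes differed between the hairpin and TRi-1. KDR, a VEGF receptor, went from 0.471 ± 0.111 to 8.24 ± 0.727 CPM with the hairpin (log2 change 4.10 ± 0.26), and stood at 0.43 ± 0.32 with TRi-1 (adjusted p = 0.391). The chemokine receptor CXCR4 changed by 3.01 ± 0.17 and by 0.52 ± 0.17 (adjusted p = 0.0554; called after the GC correction at 0.0137 and against the senescent control at 0.0169). ID4, an inhibitor of differentiation, fell by 3.87 on the log2 scale with senescence and rose by 3.75 ± 0.31 with the hairpin. The matrix link protein HAPLN1 fell by 3.23 on the log2 scale with TRi-1 and stood at 0.58 ± 0.23 with the hairpin (adjusted p = 0.0511). The test of the difference gave hairpin minus TRi-1 effects of 3.67 ± 0.43 for KDR, 2.49 ± 0.24 for CXCR4, 4.14 ± 0.55 for ID4 and 3.81 ± 0.42 for HAPLN1, with adjusted p-values from 7.67e-06 (CXCR4) to 4.51e-05 (ID4). The macrophage and lysosome gene CD68 went from 20.9 ± 5.12 to 75.2 ± 4.09 CPM with senescence and was at 27.7 ± 9.66 CPM with the hairpin.

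Within groups, libraries spread along a shared axis: the first component of the deviations from group means took 39.1% of their variance. Its gene loadings had a Spearman correlation of 0.741 with transcript GC content and -0.134 with length, so a GC bias of the libraries may account for the axis. Depth is argued against by a Pearson correlation of -0.0767 between library score and total count over 15 libraries (permutation p = 0.788), a Spearman correlation of 0.0393 (permutation p = 0.894) and -0.101 without the 2 farthest libraries, the single relation of this kind computed. A batch shared by replicate number is argued against by 6 of 30 same-number pairs with deviations correlated above 0.1. No biological explanation was tested, and a correlation across genes cannot say at which step the bias arose.

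Senescent DMSO and senescent control libraries differed in 2595 genes, with mitosis genes higher and cholesterol synthesis lower in DMSO. After GC correction 5267 genes were called. Calls rose in every comparison after it, as from 3176 to 5513 with TRi-1, so this count alone decides nothing on GC bias. Of the 2595 calls, 2515 were kept, with 0 changes of sign. That argues against median shifts shared by genes of like GC content as the whole cause. It cannot decide on biases particular to single genes. A larger share of growing cells in the DMSO cultures could raise mitosis genes. In that case other genes low in TRi-1 libraries should have moved the same share of the way to the growing level, and the ratio of median shares was 0.0788 (95% interval -0.151 to 0.259). The interval ran past the bound set for this test and rested on 3 mitosis genes, so this stays open, and an effect of the vehicle cannot be told apart from a separate set of cultures, since the design gives each a single group.

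The beta-like globin genes were higher in senescent than in growing cells: HBG2 stood at 23.7 ± 2.24 CPM (n = 3) against 0.0607 ± 0.0725, and fell to 2.73 ± 0.576 with the hairpin and from 17.5 ± 1.52 to 1.14 ± 0.181 with TRi-1. Alpha globin counts were 0% of 2374 beta-like counts in the senescent control, which allows up to 0.126% by counting error alone. HBA2 had 0 counts in all 15 libraries, and HBA1 at most 5 counts in a group. These alpha globin genes are similar in sequence, and the treatment of reads shared between similar genes is not given. The 0% argues against blood RNA only if such reads were counted. Reads shared between HBG1 and HBG2 are argued against as the whole cause by 3 of 3 further genes, HBB, HBD and HBE1, that were called higher, though the split of reads between HBG1 and HBG2 stays uncertain. After GC correction the log2 change of HBG2 with TRi-1 was -3.93, against -3.92 before. The correction takes out only the median shift of genes of like GC content. It thus shows that such genes did not share this fall, and cannot decide on a bias particular to HBG2. Expression of the beta-globin locus within the senescent fibroblasts may be a hypothesis that stays open, and HBE1 was not called with the hairpin (adjusted p = 0.129).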
